A study of Mus musculus with 30 samples.

How the data were processed

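Gene expression was measured by single-channel Affymetrix exon arrays on total RNA from mouse embryonic fibroblasts, which are connective tissue cells grown out of mouse embryos. The cells were harvested at passage 2, per the labels. The authors deposited 1 table of 26003 Ensembl gene IDs by 30 arrays. The deposited log2 values were made by the authors by RMA (robust multichip average), which quantile-normalizes the arrays together, with probes regrouped by a Brainarray custom chip definition (MoEx10stv1, version 14.1.0), per the series' design text. The log2 scale was inferred from the values, which run from 1.11 to 12.8. The genome build mm9 is named in the submitters' processing notes, and the RMA software is not given in the sources used here. Gene-level medians still differed between arrays, from 5.66 to 5.93, and the standard deviation of an array's values, called array contrast here, ran from 2.13 to 2.30. RMA applies quantile normalization to probes, and whether this explains the differing medians was not tested. A detection call for dim genes was not given in the sources used here, so no gene could be called undetected. The number of arrays and lines limits the precision.

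The 30 arrays came from 16 lines, each named after 1 mouse in the labels: 9 wild-type lines with 1 array each and 7 Aip knockout lines with 3 arrays each. The 3 arrays of a line were averaged and counted as 1 replicate. Nothing in the labels says whether they came from separate cultures. No pair of arrays held identical values. Knockout and wild-type lines were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean expression), and p-values were adjusted by Benjamini-Hochberg over all 26003 IDs. A gene was called at an adjusted p under 0.05. The authors' design text names a 2-way ANOVA with Benjamini-Hochberg control and gives no second factor. Genes that differed among the knockout lines were found with limma's moderated F test over 21 arrays.

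Line names begin with K or with k, and the labels do not say what the letter case stands for. Both genotypes were present under each, so the comparison was repeated with the letter case as a block and within each letter case, and the interaction of genotype with letter case was tested. Some lines also share the number that follows the letter. In the 5 pairs of a wild-type and a knockout line with the same number, deviations from the genotype means correlated at 0.29 to 0.59, and at 0.098 to 0.30 once letter case was also taken out. The number was therefore treated as pairing the lines in alternative fits, as a fixed or a random block. The main fit, its intervals, the fits without 1 line and the fits to splits of the lines held no term for the number. The pairing comes from the line names, whose meaning the labels do not state.

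The deposited IDs carry no gene symbols, and the gene table used here (GRCm38.p6) holds 49997 genes with no Ensembl IDs, so 0 of 26003 IDs were matched to a symbol or position. The planned reading of Aip itself, 30 gene lists (Gαi and cAMP signalling, the aryl hydrocarbon receptor and HSP90 systems, fibroblast programmes and markers of other cell types), the genes within 5 Mb of Aip and the exclusion of sex chromosome genes were therefore not analysed here. The rule for named genes, fixed before the data were examined, took the largest rises and falls among called genes outside the dimmest 1 in 3 (a mean over lines of at most 4.68). It asked for a symbol. Its size criterion alone was applied and was cut to 2 IDs in each direction, fewer than the rule asked for. These 4 IDs are followed throughout. The second of the falling IDs lies among these dim genes and was chosen after its values were seen.

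The tests were checked on simulated values with the real means and residual spread over 26003 genes, of which 200 were changed. Real letter case shifts were kept only for the comparison of genotypes and the interaction. For the F test no other differences among the knockout lines were simulated. Noise was drawn independently for each line, while real lines of one number correlated at 0.66 in the genotype fit. That fit held no letter case term, so the 0.66 also takes in differences between K and k names. The rates below therefore do not cover resemblance between lines of one number. The comparison of genotypes recovered 78% of changes of 0.5 and 99% of changes of 1 on the log2 scale, and 83% and 99% with the letter case as a block. The interaction test recovered 82% of differences of 1 and 99% of differences of 2. The real comparison of genotypes called 14 IDs, or 24 with that block, and the real interaction test called 0. Each of these simulations called more, which makes the Benjamini-Hochberg limit on the unadjusted p less strict. Real changes of these sizes may therefore be recovered less often. The F test among knockout lines recovered 56% of genes shifted by 0.5 in 1 line and 90% of those shifted by 1. The test of K against k names recovered 86% and 96% of shifts of 0.5 and 1. Calls of genes that had not been changed numbered 8 of 185 in the comparison of genotypes, 15 of 197 with the letter case as a block, 7 of 188 in the interaction test, 18 of 164 in the F test among knockout lines and 11 of 193 in the test of K against k, or 4.3%, 7.6%, 3.7%, 11.0% and 5.7%, where 5% is the nominal limit. Alternatives were a single array for each knockout line, all 30 arrays with the line as a random block or as independent samples, blocks for letter case and line number, each line left out, other scalings, a filter on low genes, array weights, other variance models and other thresholds.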

Results

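The series compared embryonic fibroblasts of mice lacking Aip with wild-type fibroblasts. Aip encodes the aryl hydrocarbon receptor-interacting protein, an HSP90 co-chaperone whose inherited loss predisposes to pituitary tumours, and the series title places the question in signalling through Gαi, the G protein subunit that lowers cAMP. Expression of 26003 Ensembl gene IDs was read on 30 arrays, from 9 wild-type lines with 1 array each and 7 knockout lines with 3 arrays each. Array medians lay between 5.66 and 5.93 on the log2 scale. The IDs were not paired with gene symbols in the sources used here. The level of Aip in each line, which would check the genotype labels, and the Gαi and cAMP genes were therefore not analysed here, and results are given by Ensembl ID.

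The number of genes that separated the genotypes depended on how lines with the same number in their names were treated. Of 26003 IDs, 14 differed between knockout and wild-type lines, 12 higher and 2 lower in the knockout, in the fit without a block (limma, adjusted p under 0.05 after Benjamini-Hochberg). With the line number as a random block over all 16 lines 201 IDs were called, 146 higher and 55 lower, and these held all 14. With the number as a fixed block, which rests on the 4 numbers that hold both genotypes, 16 IDs were called and 6 of them were among the 14. Each number lies under a single letter case, so a block on the number also takes up differences between K and k names. The effects of number and letter case on these counts were not separated. The values that follow are from the fit without a block, with the fixed block given for each named ID. The largest rise was that of ENSMUSG00000090698, from 5.49 ± 0.38 (SD, n = 9 lines) to 6.84 ± 0.59 (SD, n = 7 lines), or 2.54-fold (log2 fold change 1.34, SE 0.22, limma adjusted p = 0.028). With the fixed block its log2 fold change was 1.02 and it did not pass (limma adjusted p = 0.17). ENSMUSG00000074303 rose 2.25-fold, from 7.21 ± 0.30 to 8.38 ± 0.39 (log2 fold change 1.17, SE 0.16, limma adjusted p = 0.0038). It did not pass with the fixed block either (log2 fold change 1.10, limma adjusted p = 0.085). ENSMUSG00000024847 fell by 1.14 on the log2 scale (SE 0.062), from 6.51 ± 0.10 to 5.37 ± 0.14, so that wild-type lines were 2.21-fold higher, and it had the smallest adjusted p of all IDs (limma, 2.0e-08). It stayed called with the fixed block (limma adjusted p = 0.00042). ENSMUSG00000040747, a dim gene, fell by 0.64 (SE 0.10), from 4.77 ± 0.23 to 4.13 ± 0.18 (limma adjusted p = 0.022). With the fixed block its log2 fold change was -0.62 and it did not pass (limma adjusted p = 0.058).

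**Figure D1:**
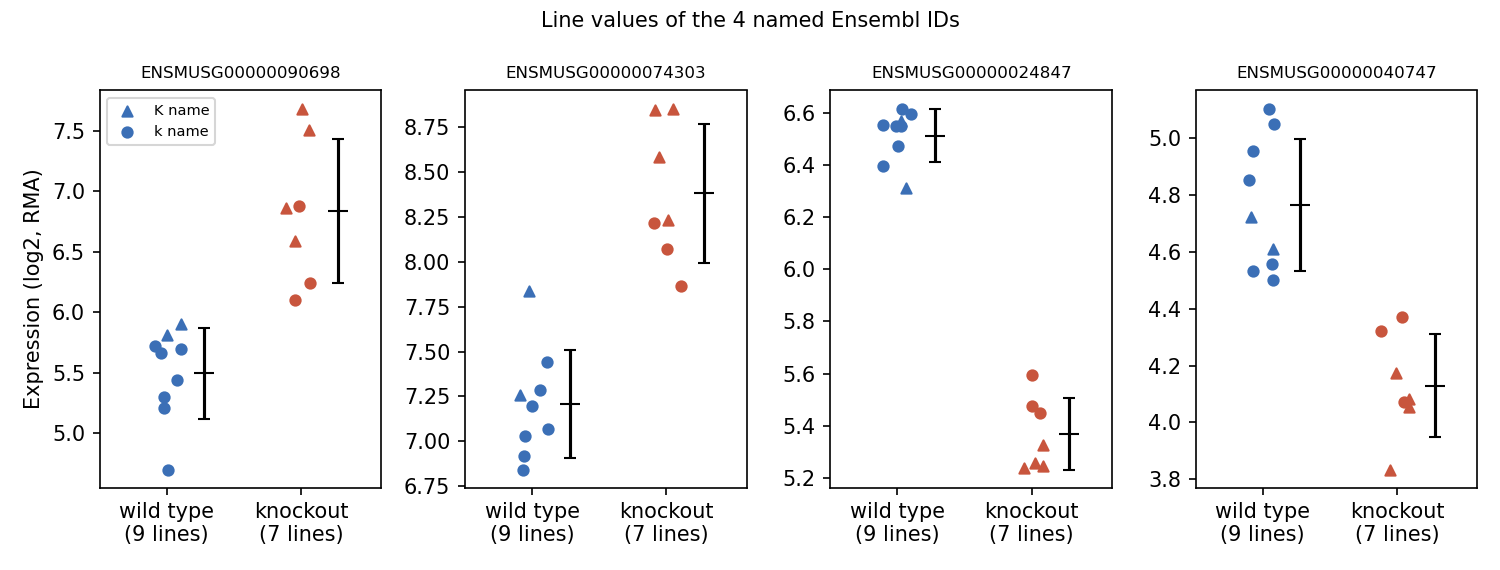
Expression (log2 RMA value, vertical axes, one panel for each Ensembl ID) in wild-type and knockout lines; each point is 1 line, triangles are K names and circles k names, and the black bar is the mean with the SD over 9 or 7 lines. In each panel every knockout line lies outside the range of the wild-type lines, above it for ENSMUSG00000090698 and ENSMUSG00000074303 and below it for ENSMUSG00000024847 and ENSMUSG00000040747. The IDs were chosen from these same values for the size of their change.

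For all 4 of these IDs the 7 knockout lines lay outside the range of the 9 wild-type lines. The single arrays did so too: 21 of 21 knockout arrays lay above the wild-type range for ENSMUSG00000090698 and below it for ENSMUSG00000024847 and ENSMUSG00000040747, and 20 of 21 lay above it for ENSMUSG00000074303. Knockout lines varied most in ENSMUSG00000090698, from 6.10 in k349_8 to 7.69 in K728_6, against an SD of 0.11 between arrays of a line. In ENSMUSG00000024847 they stayed between 5.24 and 5.59. The other 10 called IDs rose by 0.30 to 0.87 on the log2 scale, or 1.23-fold to 1.83-fold. Of these, ENSMUSG00000028525, ENSMUSG00000021684 and ENSMUSG00000025584 had limma adjusted p of 1.3e-06, 6.1e-06 and 1.5e-05. They stayed called with the fixed block (limma adjusted p = 0.00096, 0.022 and 0.022) and whichever line was left out. ENSMUSG00000023034 and ENSMUSG00000032436 also passed with the fixed block (limma adjusted p = 0.00076 and 0.0050), and the rest of the 10 did not. Over all 26003 IDs, lines of the genotypes did not overlap in 31. If all splits of the 16 lines into 7 and 9 were equally likely, 0.0175% of IDs would not overlap. That percentage ignores shared line numbers and the uneven spread of the genotypes over letter case.

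Most IDs, dim ones included, had intervals confined to small log2 differences in the fit without a block. No detection call was given, so a narrow interval of a dim gene may not bound the change in its RNA. The 95% interval of the log2 fold change lay within -1 and 1 for 25888 IDs (99.6%) and within -0.5 and 0.5 for 24564 IDs (94.5%), with a median SE of 0.074. At an unadjusted p under 0.05 there were 1569 IDs (6.03% of those tested), 818 higher and 751 lower in the knockout, and 2297 with the letter case as a block, 3320 with the line number as a fixed block and 3370 with it as a random block. Only 3 called IDs changed by 1 or more on the log2 scale, namely ENSMUSG00000090698, ENSMUSG00000074303 and ENSMUSG00000024847. The calls depended on single lines: 5 of the 14 stayed called whichever line was left out, ENSMUSG00000074303 and ENSMUSG00000024847 among them, while ENSMUSG00000090698 was called in 8 and ENSMUSG00000040747 in 9 of 16 such fits. The count fell to 5 without knockout line K728_6 and rose to 24 without wild-type line K680_2.

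**Figure D2:**
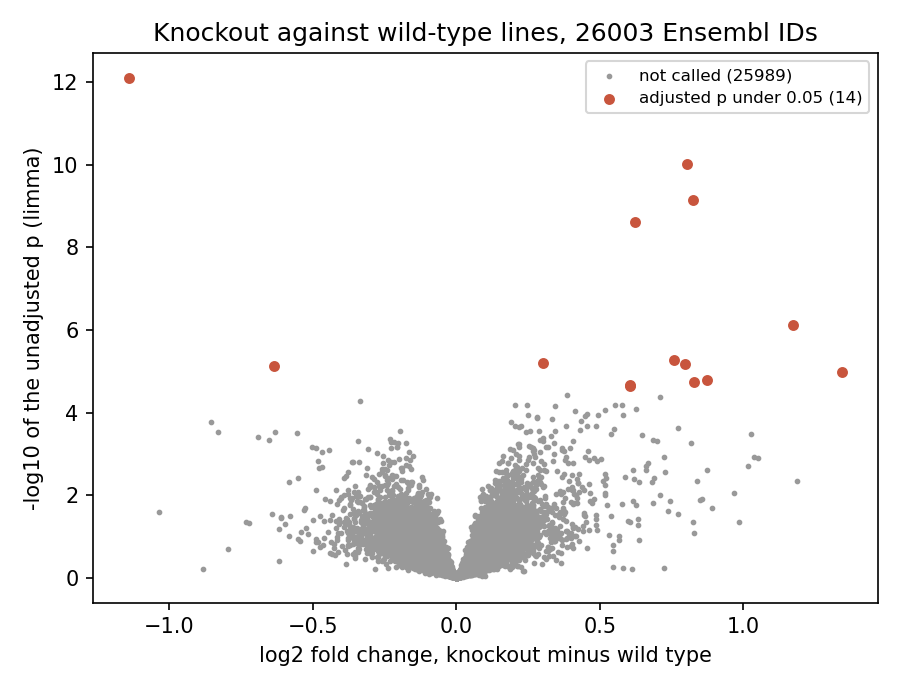
The log2 fold change of knockout minus wild type (horizontal axis) against -log10 of the unadjusted limma p (vertical axis) for 26003 IDs; red points are the 14 IDs with an adjusted p under 0.05. Of the red points 12 lie to the right of 0 and 2 to the left, and the topmost is ENSMUSG00000024847 with a log2 fold change of -1.14.

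The line names split the samples more than the genotype did. Lines named with K (4 knockout, 2 wild type) and with k (3 knockout, 7 wild type) differed in 9376 of 26003 IDs in a fit that included genotype (limma adjusted p under 0.05), by a median of 0.24 on the log2 scale. With the line number as a random block, which allows for lines that share a number, 3824 IDs differed, 3823 of them among the 9376. Differences of 1 or more were found in 26 IDs of the fit without that block. After removal of a trend on array contrast, estimated between arrays of a knockout line, 4956 IDs differed, 4146 of them among the 9376. The median difference of the 9376 was then 0.15. Of the 9376, 6760 (72.1%) were lower in K lines, but the median of all IDs was itself 0.094 lower there (K minus k, -0.094). With each array centred on its median 6435 IDs differed and 34.2% of them were lower in K lines, and after a repeated quantile normalization 6118 differed and 48.7% were lower, so the predominant direction of this difference changed with the scaling. The first principal component of the arrays (34.9% of the variance) averaged -17.0 ± 4.1 (SD) over 6 K lines and 12.7 ± 11.1 over 10 k lines. It also varied with array contrast between arrays of 1 line. In k358_6 it was 39.4 at a contrast of 2.13 and -1.8 at 2.27, and in K680_6 5.1 at 2.19 and -27.4 at 2.28. The k line k431_6, with the highest contrast of all lines (2.28), scored -12.2.

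**Figure D3:**
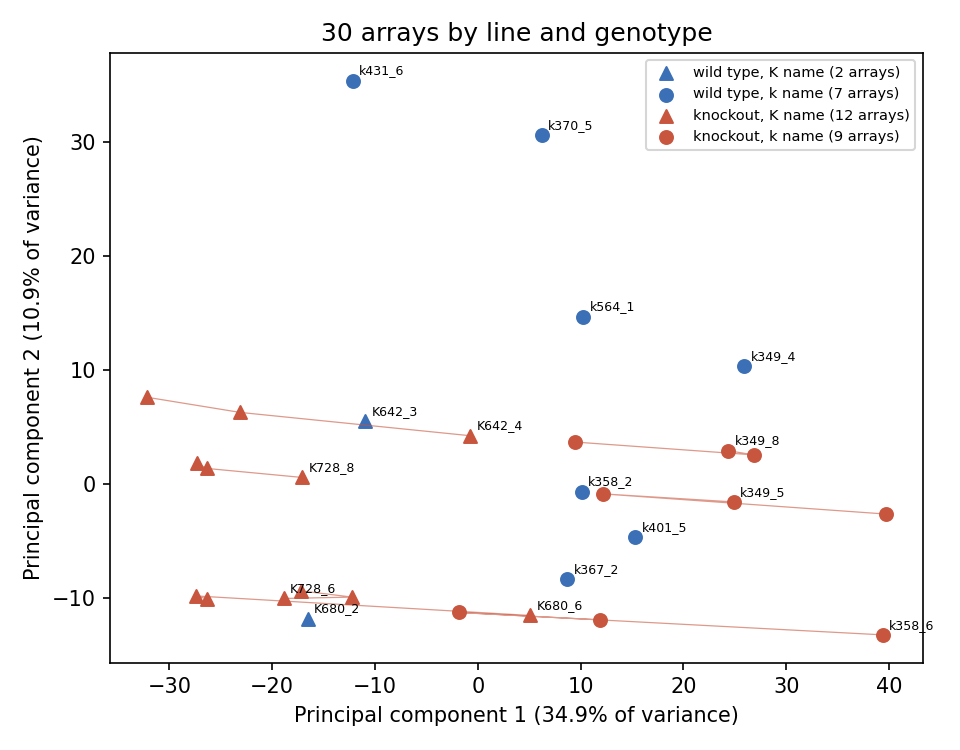
The first and the second principal component of the 30 arrays (34.9% and 10.9% of the variance, component scores on both axes); colours give the genotype, triangles K names and circles k names, thin lines join the 3 arrays of a knockout line, and labels name the line. K arrays lie mostly to the left and k arrays mostly to the right, arrays of a knockout line spread along the horizontal axis by up to 41.2, and the wild-type lines k431_6 and k370_5 stand highest, at 35.4 and 30.6.

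The knockout effect was therefore also estimated with the letter case as a block. It then gave 24 IDs, 20 higher and 4 lower, 13 of them among the 14. The named IDs kept their calls: the log2 fold change was 1.13 (SE 0.19) for ENSMUSG00000090698, 0.99 (SE 0.12) for ENSMUSG00000074303, -1.08 (SE 0.052) for ENSMUSG00000024847 and -0.57 (SE 0.10) for ENSMUSG00000040747, with limma adjusted p between 9.9e-09 and 0.042. Within the k lines alone 9 IDs were called, 7 of them among the 14. Within the 6 K lines limma called 0 IDs, with 2149 at an unadjusted p under 0.05. The log2 fold change in K and in k lines was 1.30 and 1.02 for ENSMUSG00000090698, 1.08 and 0.94 for ENSMUSG00000074303, -1.17 and -1.03 for ENSMUSG00000024847, and -0.63 and -0.54 for ENSMUSG00000040747. The test of the difference itself, the interaction of genotype with letter case, called 0 IDs (limma, smallest adjusted p = 0.90), with 1170 at an unadjusted p under 0.05.

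Lines of the same genotype also differed from each other. Among the 7 knockout lines 11568 IDs (44.5%) differed by more than the spread between arrays of a line (limma moderated F test, adjusted p under 0.05), and 535 of these had line means at least 1 apart on the log2 scale. The 7 lines are 4 K and 3 k lines and the test held no letter case term. The count therefore also takes in differences between K and k names. Of the 14 IDs that separated the genotypes, 12 also differed among the knockout lines and 5 between K and k names. The median SD over IDs was 0.12 between arrays of a line, 0.13 between knockout line means and 0.15 between wild-type lines, the latter from single arrays. Leaving out the third array of each line took the count among knockout lines to 6658.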

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

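The fits with the contrast trend removed, those without wild-type lines k370_5 and k431_6, the low filter combined with the letter case block and all alternatives for K against k were chosen after seeing the data. The 14 IDs called between genotypes became 24 with the letter case as a block, 201 with the line number as a random block, 9 in k lines alone and 0 in K lines alone. They became 233 with the line as a random block over 30 arrays, 414 with 30 arrays as independent samples, 1040 with a 2-way ANOVA of genotype and line number over 30 arrays (the second factor is a choice made here, since the design text gives none), 141 with array weights, 5 at an adjusted p under 0.01 and 3 with a change of 1 or more. The letter case block gave 48 IDs without the dimmest 1 in 3 genes and 112 without k370_5 and k431_6. Fits that use 30 arrays take the 3 arrays of a line as added samples or model their correlation. In the other 11 of 23 settings the count stayed within 1.5 times. Leaving out 1 line gave 5 to 24 IDs: 9 without K642_4, 24 without K680_2, 8 without K680_6, 5 without K728_6, 6 without K728_8, 9 without k349_5, 8 without k358_6, 7 without k401_5 and 7 without k431_6. The fold changes of the 4 IDs followed throughout kept their sign in all 146 refits and passed the threshold in 120. Genes that differ among knockout lines numbered 6658 to 10548 when the same-numbered array of each line was left out. Genes that differ between K and k fell to 4956 with the contrast trend removed to 6118 with quantile normalization repeated, to 3824 with the line number as a random block and to 2700 with that block and the contrast trend removed. The interaction stayed at 0 in both alternatives. Beyond what the text says, the cause of these changes was not tested. The settings fixed before the data were examined for Aip, the gene lists, the genes near Aip and the X and Y chromosomes were not run.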

Other observations

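The fit of the genotypes with the letter case as a block was fixed before the data were examined, but its use as a test of the letter case as the source of the genotype calls, the comparison of K with k names, the removal of the contrast trend with the splits that follow it, the splits that keep lines of one number together, the line number as a random block for K against k, the contrast covariate and the fit without k431_6 and k370_5 were chosen only after the results they bear on had been seen.

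Wild-type and knockout lines that share a number in their names resembled each other beyond genotype and letter case. The deviations of their values over 26003 IDs correlated at a mean of 0.21 in 5 such pairs, against -0.043 in 24 pairs of the same letter case with other numbers (one-sided permutation p = 0.0024, 9999 permutations of numbers within genotype and letter case). Taking out the group means ties these averages to each other, so the -0.043 is no separate baseline. The permutations used the same deviations. The pairs of k349_4 with k349_5 and with k349_8 share a line, and the 2 wild-type K lines have opposite deviations (correlation -1). The 2 pairs of knockout lines with the same number correlated at -0.42 (K728_6 and K728_8) and -0.20 (k349_5 and k349_8), where taking out the mean of their 4 and 3 lines alone gives -0.33 and -0.50, so one lay below and the other above that value; whether knockout lines with the same number resemble each other was not tested. This is consistent with a shared origin of such lines, as a litter or a day of preparation would give, and the labels do not say which. The wild-type lines k431_6 and k370_5 scored 35.4 and 30.6 on the second principal component, and the next line, k564_1, scored 14.7. Without them 12 IDs were called between genotypes, 8 of them among the 14. The variance between wild-type lines was 1.31, 1.11 and 1.30 times that between knockout lines with array 1, 2 and 3 of each knockout line, and permuted genotypes gave ratios as far from 1 with two-sided permutation p of 0.13, 0.57 and 0.17, so no dependence of the spread on genotype was shown.

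The 14 IDs called between genotypes were weighed first. In 100 splits of the 16 lines into 7 and 9, 2 gave 14 or more, the real one included, and the highest other gave 20; that split had 1 K line among its 7 and so partly followed the letter case, while the 22 other splits that parted as many same-numbered pairs as the real one gave at most 0. Among 100 splits that kept 4 lines under K and 3 under k, 1 (the real one, with 24 IDs) gave as many and the highest other gave 0. Chance is thus an unlikely source of the 24, though 100 splits cannot exclude it. Tables argue against the letter case (13 of 14 IDs stayed called in the blocked fit), array contrast (14 stayed called after its trend was removed) and the averaging of 3 arrays in knockout lines only (at least 11 stayed called with 1 array). Genes carried along with the targeted chromosome segment stay open, because 0 of the 14 IDs had a position in the table used here, and the loss of Aip, which the design names, stays open beside it. With the line number as a fixed block, which rests on the 4 numbers that hold both genotypes, 6 of the 14 stayed called. With the number as a random block all 14 did. Resemblance between lines of one number therefore also stays open as a source of some calls. A candidate explanation for part of the 14 is thus any of these, and the tables do not choose between them.

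The difference between K and k names was weighed next. No other of 100 splits of the lines into 6 and 10 reached 9376 IDs (the real split is the 1 that did), and the highest other, 9207, held 5 of the 6 K lines. K arrays had a higher contrast (2.26 ± 0.032, SD over 14 arrays of 6 lines) than k arrays (2.20 ± 0.039, 16 arrays of 10 lines). Repeat arrays of a line were counted singly in these values. Removing the contrast trend estimated between arrays of a knockout line left 4146 of the 9376 IDs called. It took their median difference from 0.24 (median SE 0.060) to 0.15 (median SE 0.053), because the differences shrank and not because their errors grew. Array contrast may therefore account for part of the difference. After the removal 4956 IDs were called, and 1 of 100 splits, the real one, gave as many (highest other 2089). The removed trend was linear and estimated within knockout lines, and the splits were not chosen to follow contrast. Whether array contrast accounts for all of the difference was therefore not settled. Each number lies under a single letter case, so splits that part lines of one number are too lenient a comparison. Among 100 splits into 6 and 10 lines that keep lines of one number together, drawn from 114, again 1, the real one, reached the real count, both in the deposited values (highest other 7666) and after the removal of the contrast trend (highest other 3360). Chance is thus unlikely, but 100 splits cannot exclude it for a comparison chosen after the data were seen. Of the 99 others 17 and 15 called any ID, and in both settings the highest had 0 K lines among its 6 and so partly followed the letter case. With the line number as a random block 3824 IDs were called, and 2700 with the contrast trend removed as well. The labels give no meaning to the letter case, so no biological explanation was tested.

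The differences among knockout lines were weighed last. When the 21 arrays were assigned at random to 7 groups of 3, 1 of 100 assignments, the real one, reached 11568 IDs, and the highest other gave 4329. The arrays of a line repeat each other, which fixes this outcome, so the count shows only that lines differ by more than repeated arrays do. With array contrast as a covariate 10003 of these IDs stayed called, which argues against contrast as their only source. The F test held no letter case term, so differences between K and k names are part of its count and were not separated from it. Differences between animals, between preparations and in the cell makeup of each culture stay open and were not tested.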
